A study of Mus musculus with 3 samples.

How the data were processed

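Ly6Chi monocytes were sorted from mouse livers 24 h after acetaminophen was given to induce acute liver injury. Per the labels' protocols, male C57BL/6 mice aged 8 weeks were fasted for 12 h, received 300 mg/kg acetaminophen into the peritoneum, and had chow back after 2 h. There were 3 libraries. The 2 control libraries, numbered 1 and 3 in the labels, came from mice with floxed but undeleted Commd10. The single knockout library, numbered 4, came from mice in which the LysM-Cre driver, carried at the Lyz2 locus, deletes Commd10 in myeloid cells. The labels do not say whether a library held cells of a single mouse, so p-values measure only the spread between these libraries, which may be technical.

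Single cells were captured in droplets, and 3' ends of transcripts were sequenced with unique molecular identifiers (UMIs), per the series' design text. The deposited matrices hold raw UMI counts per gene and cell barcode; per the submitters' processing notes and the file headers the authors made them with Cell Ranger 3.0.2, after bcl2fastq, on genome build GRCm38. The lowest total of any deposited barcode was 500 UMIs in each library, and the filter behind it is not given in the sources used here. The matrices held 4814, 8109 and 5152 barcodes for control 1, control 3 and knockout 4, beside 4860, 8149 and 5229 cells stated in the design text. Of the 53802 gene identifiers, 53706 (99.8%) were found in GENCODE M21, from which coordinates on GRCm38 were taken. No deposited table assigned cells to types, so clusters were built and named here.

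Barcodes with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. Scrublet, run per library through scanpy 1.11.5, called 0 doublets in every library, so doublets were not removed. This does not show that none were present, and why none was called was not tested. Counts were scaled to 10000 per cell and log transformed, the 2000 most variable genes were reduced to 30 principal components, and cells were clustered with the Leiden method (leidenalg 0.10.2, resolution 0.8) on a graph of 15 nearest neighbours, all libraries together and without integration. A cluster was given a name only if at least 3 fixed markers of that type were detected in 25% or more of its cells at 1.5 times or more the level of other cells, at least 1 of them among its 10 leading genes, and no other type had more markers among those 10. Clusters named T cell-like, B cell-like and neutrophil-like were left out of the monocyte-macrophage sums (37, 46 and 24 cells). Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only.

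Cells were not treated as replicates. UMI counts were summed per library over monocyte-macrophage cells, over all cells that passed, and over each cluster with at least 200 cells in every library. The sums were compared with edgeR 4.0.16 (R 4.3.3): TMM factors, filterByExpr, glmQLFit and a two-sided glmQLFTest of knockout against control, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 1 residual degree of freedom the spread came from the 2 control libraries and from moderation across genes (6.41 prior degrees of freedom; common biological coefficient of variation 15.9%), and the lone knockout library was assumed to vary like the controls. Leaving out a control leaves 1 library against 1, which gives values and no test. Fold changes are log2 values of knockout over control with standard errors (SE). Levels are CPM, UMI counts divided by the TMM-scaled total of the library and multiplied by 1e6. The method was tested on simulated counts for the monocyte-macrophage comparison (14807 genes, 200 of them changed in each of 5 runs). It called 66.4% of genes changed by 1 log2 unit and 99.6% of those changed by 2, and 4.89% of its calls were false. Only genes over 5 CPM were changed, and each gene had the spread of the trend at its level. These rates therefore do not cover lower genes or genes that vary more than the trend.

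The groups, tests, gene lists, markers and named-gene rule were fixed before the data were examined. There were 21 functional lists: type I interferon response; inflammasome and IL-1; neutrophil-like monocyte; lipid-associated macrophage; macrophage maturation; Ly6Chi monocyte identity; MHC class II presentation; MHC class I presentation; NF-kB targets, cytokines and chemokines; glycolysis and hypoxia; nuclear oxidative phosphorylation; mitochondrially encoded genes; ribosomal proteins; lysosome; COMMD, CCC and retriever complexes; copper handling; tissue repair factors; cell cycle; immediate-early and dissociation genes; NRF2 and antioxidant genes; and cholesterol and LXR. A further 20 lists held cell type markers. Lists were tested with limma 3.58.1 camera (preset correlation 0.01, and with an estimated correlation) and fry; camera was adjusted over the 21 functional lists and over the cell type lists separately, fry over all lists together, and their members were also adjusted over the list alone. List medians were ranked among those of 10000 random lists matched on mean expression. The text names Commd10 and Lyz2; up to 12 genes with the largest rise and 12 with the largest fall among genes that passed, had 20 CPM or more in a group and moved the same way against both controls; where fewer passed, genes in order of p to make up 6 per direction; up to 4 members of each functional list in order of p; and up to 3 members of each cell type list by level. Predicted genes and immunoglobulin or T cell receptor segments were outside this rule, and any other gene is said to have been chosen after its values were seen. Some genes that this rule takes are not reported here.

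Alternatives fixed beforehand were DESeq2 1.42.0, RLE factors, library totals without factors, no low-count filter, all barcodes, a stricter cell filter (1000 genes, 5% mitochondrial UMIs), doublets kept, cells thinned to 3000 UMIs (498, 679 and 737 shallower cells left out in control 1, control 3 and knockout 4), monocyte-like cells only, each control left out, Leiden resolutions 0.4 and 1.2, clustering without the genes called between groups, and clustering after centring each library. Sums without the low-UMI cluster, without cells above 2 times their library's median UMI count, and without cluster 5 were added after seeing the data, and so was the recomputation of the cell type lists under these settings.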

Results

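Transcriptomes of single Ly6Chi monocytes, the inflammatory monocytes that enter the liver after injury, were compared between mice lacking COMMD10 in myeloid cells and floxed controls 24 h after acetaminophen. COMMD10 belongs to a family of proteins that act in endosomal sorting and copper handling, and the comparison asked how its loss changed monocytes in the injured liver. The 2 control libraries held 40092348 UMIs in 4814 barcodes (control 1) and 72867668 UMIs in 8109 barcodes (control 3), and the knockout library held 30302932 UMIs in 5152 barcodes (knockout 4). After filtering, 4115, 7449 and 4457 cells remained, with medians of 8770, 8160 and 6865 UMIs and of 2778, 2631 and 2363 genes per cell. The knockout library was thus the shallowest per cell, and cells with over 2 times their library's median UMI count made up 8.31% and 11.05% of control cells but 2.45% of knockout cells. Monocyte-macrophage cells numbered 4078, 7403 and 4433.

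Commd10 (chromosome 18, 46958816 to 47234284, plus strand) was detected in every library at a low level. It stood at 17.2 CPM in control 1, 10.3 CPM in control 3 and 8.62 CPM in knockout 4 (693, 744 and 250 UMIs), a log2 fold change of -0.67 ± 0.31 (SE; 2 control and 1 knockout libraries) that did not pass the test (edgeR, adjusted p = 0.614). A 3' tag can lie outside the deleted part of the gene, so this value does not check the genotype. Lyz2 (chromosome 10, 117277331 to 117282321, minus strand), the lysozyme gene that carries the Cre driver, stood at 14997 and 11592 CPM in the controls and 6619 CPM in the knockout library. Its log2 fold change of -1.01 ± 0.22 did not pass (adjusted p = 0.199), passed with DESeq2 (adjusted p = 0.00223), and lay between -1.18 and -0.68 in the 7 clusters tested. Neither value goes against the labels.

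In monocyte-macrophage cells of the knockout library, the chemokine genes Cxcl3 and Ppbp and several genes of the glycolysis and hypoxia list were higher, and the chemokine gene Cxcl9 was lower. Of 14807 genes tested, 27 were higher and 1 was lower. The largest rise was that of Cxcl3, a chemokine that attracts neutrophils (chromosome 5, 90786103 to 90789600), from 10.2 and 8.47 CPM in the controls to 205 CPM (log2 fold change 4.46 ± 0.17, adjusted p = 0.000208). Ppbp, a chemokine gene of the same chromosomal stretch that platelets also express in abundance (90768518 to 90770063), rose from 2.91 and 2.96 to 29.8 CPM (3.34 ± 0.18). Egln3, a prolyl hydroxylase that acts on the hypoxia-inducible factors, rose by 2.68 ± 0.19, and Hilpda, a hypoxia-induced lipid droplet protein, rose from 37.6 and 25.9 to 139 CPM (2.14 ± 0.22). The heparan sulfate proteoglycan gene Sdc1 rose by 2.68 ± 0.22, the interferon-induced membrane protein gene Ifitm1 by 2.01 ± 0.14, the triglyceride synthesis gene Gpat3 by 1.81 ± 0.17 and the interleukin receptor chain Il7r by 1.56 ± 0.17. The oxidoreductase Ero1l (1.74 ± 0.14), the mitophagy receptor Bnip3 (1.74 ± 0.15), the glucose transporter Slc2a1 (1.63 ± 0.17) and the hypoxia-induced Ankrd37 (1.57 ± 0.15) rose as well.

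The 1 gene that fell was Cxcl9, a T cell chemokine induced by interferon gamma (chromosome 5), from 22.5 and 27.6 CPM to 1.17 CPM (-4.42 ± 0.28, adjusted p = 0.00252). The next genes in order of p did not pass: Ramp1, a calcitonin-family receptor subunit, at 73.1, 76.0 and 36.3 CPM in control 1, control 3 and knockout 4 (-1.04 ± 0.16, adjusted p = 0.0691); the chemokine receptor Cx3cr1, a marker of monocyte maturation, at 354, 304 and 152 CPM (-1.11 ± 0.18, adjusted p = 0.0798); Gdf15 (-1.04 ± 0.17); Fosb (-1.08 ± 0.18); and St3gal5 (-1.07 ± 0.18). All 27 genes that rose were above each control, with log2 fold changes from 1.18 to 4.46. The number of calls changed with the tool: DESeq2 called 98 higher and 21 lower, including all 28 of edgeR's. Without the cells of cluster 5, described further on, edgeR called 0 genes. Of 14714 genes tested there 629 had an unadjusted p under 0.05, a share below 0.05 that by itself shows no excess. With those cells it was 1275 of 14807. Without cluster 5 the 27 genes still all had positive values, with a median log2 fold change of 1.27 instead of 1.80 and a median SE of 0.18 instead of 0.17. Genes with large folds lost the call too, among them Cxcl3 (2.28, adjusted p = 0.26) and Egln3 (2.06, adjusted p = 0.236), and why the calls ended was not tested. Without cells of high UMI count 9 higher and 0 lower genes remained (1207 of 14257 tested with an unadjusted p under 0.05), with the median of the 27 at 1.77.

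**Figure D1:**
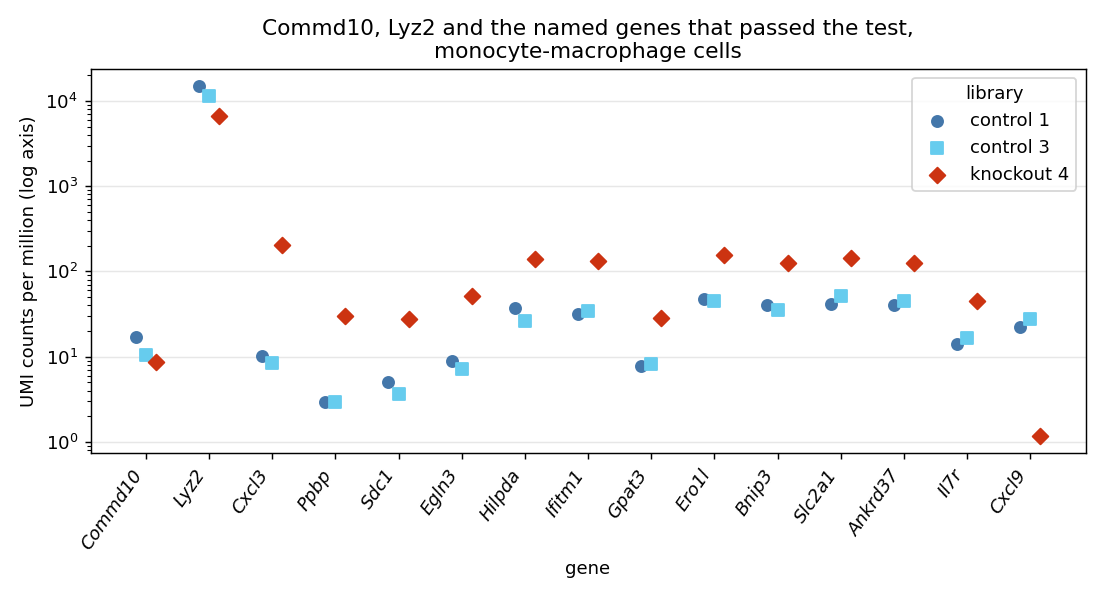
CPM (UMI counts scaled to library size, log axis) of Commd10, Lyz2 and the 13 named genes that passed the test, summed over monocyte-macrophage cells; each point is 1 library. Cxcl3 lies at 205 in the knockout library against 10.2 and 8.47 in the controls, and Cxcl9 at 1.17 against 22.5 and 27.6, while Commd10 (8.62 against 17.2 and 10.3) and Lyz2 (6619 against 14997 and 11592) did not pass.

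Genes of glycolysis and of the hypoxia response lay above both controls without exception. All 25 measured members were higher in the knockout library than in either control, with a median log2 fold change of 0.84 (0.74 against control 1, 0.97 against control 3), whereas the controls differed by a median of -0.20 (control 3 minus control 1). Of them, 6 passed over all genes, among them Egln3, Ero1l, Bnip3 and Hilpda, and 22 passed when adjusted over the list alone; none fell. Vegfa, the endothelial growth factor, which is also in the list of tissue repair factors, stood at 20.4, 12.5 and 47.9 CPM (1.55 ± 0.26, adjusted p = 0.0952), but at 0.52 without cluster 5 and at 0.0004 in the monocyte-like cluster alone. The median exceeded that of every one of 10000 random lists of matched expression, as did those of the tissue repair, cell cycle and neutrophil marker lists. For cell cycle genes the controls themselves differed by -0.67, so this rank does not take account of the spread between libraries. Camera with a preset correlation gave an adjusted p of 4.32e-57; the adjusted p = 0.557 with an estimated correlation, which rests on 1 residual degree of freedom, and fry gave 0.565.

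NRF2 targets, which protect cells from oxidants, were mostly higher: 11 of 12 members lay above both controls, with a median of 0.37 (0.52 against control 1, 0.28 against control 3; controls 0.21 apart). None passed over all genes and 4 passed when adjusted over the list alone, namely Hmox1, which breaks down heme, at 834, 1168 and 2551 CPM (1.35 ± 0.21, adjusted p = 0.0798), the cystine transporter Slc7a11 (1.37 ± 0.22), Prdx6 (0.82 ± 0.16) and Gclm (0.47 ± 0.15). The preset camera test called the list up, with an adjusted p of 2.18e-07, and adjusted p = 0.557 with an estimated correlation.

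Tissue repair factors had a median of 0.38, with 0.26 against control 1 and 0.82 against control 3, while the controls themselves differed by -0.40. None of 16 passed over all genes; adjusted over the list alone 7 were higher and 1 lower. Arg1, the arginase of repair macrophages, stood at 355, 128 and 1551 CPM (2.68 ± 0.47, adjusted p = 0.104), Tgm2 at 0.98 ± 0.19 and Hbegf at 1.36 ± 0.30. The call (preset adjusted p = 5.44e-06) was lost at adjusted p = 0.804 with an estimated correlation. Of 28 NF-kB targets, cytokines and chemokines, Cxcl3 alone passed over all genes, and adjusted over the list alone 7 were higher and 1 lower. The eosinophil chemokine Ccl24 stood at 309, 168 and 788 CPM (1.72 ± 0.30, adjusted p = 0.107), Ccl7 at 0.94 ± 0.19 and Cxcl2 at 0.90 ± 0.19. The list was called up (preset adjusted p = 5.51e-05; adjusted p = 0.557 with an estimated correlation) on a median of 0.01 (0.17 against control 1, 0.02 against control 3) and a mean of 0.18. The median turned negative (-0.04) with library totals in place of TMM. The preset call was lost without cluster 5, where Cxcl2 stood at -0.058. It was also lost in the monocyte-like cluster only, with Cxcl2 at -0.28 and Ccl24 at -0.42.

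Genes of neutrophil-like monocytes had a median of 0.24 (0.47 against control 1, 0.14 against control 3; controls 0.12 apart). None of 23 passed over all genes, and 5 were higher when adjusted over the list alone. Among them Lcn2, an iron-sequestering protein, stood at 129, 112 and 274 CPM (1.19 ± 0.16, adjusted p = 0.0502), Saa3 at 1.00 ± 0.15 and S100a8 at 504, 234 and 1288 CPM (1.80 ± 0.37). S100a9 stood at 60.3, 21.7 and 219 CPM (2.42 ± 0.46), with 1.85 against control 1 and 3.34 against control 3. The preset adjusted p was 4.23e-05, and adjusted p = 0.557 with an estimated correlation. Genes of lipid-associated macrophages had a median of 0.23, smaller in size than the -0.50 by which the controls differed, with 0.07 against control 1 and 0.38 against control 3. Of 22, none passed over all genes and 5 were higher when adjusted over the list alone. Among them were the protease Ctsl (0.96 ± 0.18), the lipid droplet protein Plin2 (0.65 ± 0.15), Cd9 (1.40 ± 0.34) and the fatty acid receptor Cd36 (1.28 ± 0.33). That call (preset adjusted p = 0.000873) was also lost, at adjusted p = 0.811 with an estimated correlation. The preset test no longer made it without cluster 5 (median 0.059) or in the monocyte-like cluster only (median -0.069).

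Cell cycle genes had a median of 0.66, about the distance between the controls (-0.67), with 0.25 against control 1 and 1.19 against control 3. None of 19 passed over all genes or when adjusted over the list alone. They were expressed at a low level, Birc5 at 1.04, 0.444 and 2.41 CPM, Ube2c at 0.994, 0.930 and 2.24 CPM, Ccna2 at 0.273, 0.111 and 0.793 CPM and Pclaf at 3.88, 1.12 and 6.27 CPM. The call (preset adjusted p = 4.52e-05) was made in 8 of 11 other settings and stood at adjusted p = 0.811 with an estimated correlation. Without cells of high UMI count it was lost and the direction turned, with the median at -0.030 and Ube2c at -0.32. Ribosomal protein genes were the 1 list called down, with a median of -0.13 (-0.12 against control 1, -0.18 against control 3) and 58 of 82 members below both controls; none passed, over all genes or adjusted over the list alone. Rpl38 (1253, 1135 and 672 CPM, -0.83 ± 0.17, adjusted p = 0.157), Rps29 (-0.70 ± 0.18), Rps28 (-0.68 ± 0.17) and Rpl37 (-0.54 ± 0.17) led it (preset adjusted p = 0.000133; adjusted p = 0.557 with an estimated correlation). Calls of the preset camera test were not particular to the knockout library. It called 8 of the 21 lists there, but also 12 when control 1 and 12 when control 3 was set against the other 2 libraries. Those splits hold the knockout library on the other side, so they do not measure how liberal the test is.

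The remaining 13 functional lists were not called. Macrophage maturation was called down in 6 of the 11 other settings with a test, MHC class I presentation in 4, immediate-early genes in 2 and MHC class II presentation in 1. Ly6Chi monocyte identity was called up in 1. These are preset camera calls. In the comparison itself the lists stood at adjusted p = 0.811 with an estimated correlation (0.867 for MHC class II), which was not run in the other settings. For 7 of the 13 lists the sign of the median depended on the control. The type I interferon response had a median of -0.12 (0.02 against control 1, -0.26 against control 3; controls 0.28 apart), with 0 of 38 members passing over all genes or adjusted over the list alone; Ifi47 stood at -0.43 ± 0.16 and Ifi205 at 0.76 ± 0.27. Inflammasome and IL-1 genes had a median of -0.07 (0.12 against control 1, -0.22 against control 3; controls 0.25 apart) and a mean of 0.03, and the test pointed down. The receptor antagonist Il1rn, at 80.9, 133 and 271 CPM (1.34 ± 0.26, adjusted p = 0.14), was the only 1 of 20 to pass adjusted over the list alone, and Nlrp1b stood at -0.81 ± 0.22. Macrophage maturation genes had a median of -0.11 (-0.15 against control 1, -0.0017 against control 3), with Cx3cr1 the 1 member to pass adjusted over the list alone, followed by Selenop (-0.55 ± 0.16), Axl (-0.74 ± 0.22) and Pltp (-0.65 ± 0.20). Ly6Chi monocyte identity genes had a median of 0.24, with 0.59 against control 1 and -0.03 against control 3, and the controls were 0.54 apart. Fn1, which passed adjusted over the list alone, stood at 0.66 ± 0.15, and Vcan at 0.53 ± 0.45 (1.37 against control 1, 0.0032 against control 3). MHC class II presentation had a median of -0.10 (0.13 against control 1, -0.30 against control 3; controls 0.38 apart), with H2-DMa at -0.67 ± 0.17 and Cd86 at 0.60 ± 0.18. MHC class I presentation had a median of -0.20 (-0.18 and -0.19), with Psmb9 at -0.42 ± 0.15 and Tap1 at -0.40 ± 0.15. Immediate-early and dissociation genes had a median of -0.16 (0.11 against control 1, -0.21 against control 3; controls 0.14 apart), with 4 of 22 members passing when adjusted over the list alone: Fosb, Atf3 (-0.64 ± 0.16) and Fos (-0.78 ± 0.21) below both controls and Egr2 (0.79 ± 0.19) above them.

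Copper handling genes had a median of 0.27 (0.10 against control 1, 0.29 against control 3), with the copper importer Slc31a1 at 0.50 ± 0.15 and the exporter Atp7a at 0.38 ± 0.18. Of 8 members 5 lay above both controls and 2 below both. Among the COMMD, CCC and retriever complexes the median was 0.10 (-0.0045 and 0.13, again with different signs against the controls), none of 16 members passed, and Vps29 (0.26 ± 0.16), Commd5 (0.77 ± 0.49) and Commd2 (0.15 ± 0.15) followed Commd10 in order of p. Commd5 ranged from 0.33 to 1.27 with a control left out and stood at -0.017 in thinned cells. The median was 0.06 for nuclear oxidative phosphorylation genes (-0.02 against control 1, 0.09 against control 3), with Cycs at 0.21 ± 0.17. It was 0.10 for mitochondrially encoded genes (0.05 and 0.22), with mt-Atp6 at 1.18 ± 0.33 and mt-Atp8 at -0.49 ± 0.15. Medians were 0.13 for cholesterol and LXR genes (0.19 and 0.08; Mylip -0.30 ± 0.17) and 0.00 for lysosome genes (Npc1 0.39 ± 0.15), the last turning to -0.05 with library totals. No member of these 6 lists passed over all genes, and adjusted over the list alone only Ctsl, in the lysosome list, did. Adjusted p of the preset camera test lay between 0.0579 and 0.936 over the 13 lists that were not called.

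In the sums over monocyte-macrophage cells, platelet markers had a median of 1.07 over 4 genes (1.46 against control 1, 0.94 against control 3), 3 of them above both controls. Without the low-count filter the median was 0.34 over 6 genes. Ppbp and Pf4 passed adjusted over the list alone (Pf4 160, 128 and 355 CPM, 1.30 ± 0.18, adjusted p = 0.0502), while Treml1 stood at 0.298, 0.236 and 0.241 CPM. Pf4 was also among the leading genes of macrophage-like cluster 1. Neutrophil markers, all 8 of which are also in the neutrophil-like monocyte list, had a median of 1.05 (0.64 against control 1, 1.43 against control 3; controls -0.95 apart), with S100a8, S100a9 and Lcn2 passing adjusted over the list alone, while Mmp8 stood at 0.32 ± 0.19. Camera with a preset correlation called 5 of 17 cell type lists, platelet (1.2e-13) and neutrophil (1.4e-07) markers up and erythroid, endothelial and pDC markers down, and none was called with an estimated correlation (lowest adjusted p = 0.879 with an estimated correlation). Medians against both controls, control 1 and control 3 were -0.76, -0.46 and -0.91 for erythroid, -0.80, -1.05 and -0.62 for endothelial and -2.34, -2.07 and -0.93 for pDC markers. The erythroid direction turned with all barcodes, where the list was called up (median 1.16), and the endothelial and pDC calls were each made in 5 other settings, of 10 and 9 with a test. Among erythroid markers Hba-a2 (-0.84 ± 0.22) passed adjusted over the list alone. Hbb-bs stood at 20.03, 32.4 and 16.3 CPM. Of 8 endothelial markers 6 lay below both controls and 1 above both, namely Kdr at 2.11, 2.33 and 3.17 CPM. The 4 pDC markers lay at 1.32 CPM or less in every library, Klk1 with 0 UMIs in control 3 and in the knockout library. The pDC median is the same with that gene set to the limit that a count of 0 allows (3 UMIs).

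Of the other marker lists, those of monocytes, macrophages, Kupffer cells, migratory DCs, hepatocytes and T cells had no direction that held against both controls. Monocyte markers had a median of 0.24, with 0.57 against control 1 and -0.02 against control 3 (controls 0.53 apart). Among them Chil3 stood at 0.24 ± 0.30 (0.69 and -0.11) and Plac8 at -0.01 ± 0.23 (0.26 and -0.23). Macrophage markers had a median of 0.07 (-0.10 against control 1, 0.28 against control 3), with Apoe at -0.21 ± 0.24 (0.06 and -0.45). Kupffer cell markers had a median of -0.20 (-0.03 and 0.10; Cd5l -0.26 ± 0.33) and migratory DC markers of -0.11 (0.06 and -0.42; Il4i1 0.68 ± 0.42). Hepatocyte markers had a median of -0.49, with 0.40 against control 1 and -1.02 against control 3 (Alb at 10.5, 32.7 and 14.0 CPM). T cell markers had a median of -0.07 and a mean of -0.22 but a test pointing up. Of 8 members 4 had positive values, and Il7r alone passed. The list median was -1.05 against control 1 and 1.69 against control 3, and the controls differed by -3.17. Patrolling monocyte markers had a median of -0.21 (-0.18 and -0.04; Adgre4 -0.43 ± 0.15) and cDC1 markers of -0.29 (-0.33 and -0.27), with Naaa at 0.05 ± 0.18 (0.21 and -0.10). Medians were -0.94 for cDC2 (-0.42 and -1.05; Clec10a 0.32 ± 0.23), -0.77 for B cell (-0.85 and -0.70; Cd79b, which passed adjusted over the list alone, -0.77 ± 0.23) and -2.24 for plasma cell markers (-0.79 and -2.77; Xbp1 0.40 ± 0.16). NK cell markers had a median of 0.47 (0.15 and 0.78) and a mean of -1.76 with a test pointing down. The NK cell and migratory DC lists each held 1 gene with 0 UMIs in the knockout library, and their medians were the same at the limit of a count of 0. Of stellate cell and eosinophil markers 1 gene each was tested (Dcn -0.32 ± 0.72, Ccr3 0.19 ± 0.51) and of basophil markers 0.

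Over all sorted cells, 32 genes were higher and 5 lower among 14894 tested (edgeR), 27 of them also called among monocyte-macrophage cells. Besides Cxcl9, the genes that fell were Igkc (87.2, 104 and 6.68 CPM), Jchain (9.54, 13.9 and 0.0344 CPM), Igha (56.8, 28.4 and 0.103 CPM) and Ccl5 (16.6, 16.4 and 5.71 CPM), genes of antibody-secreting cells and of lymphocytes; they were chosen after their values were seen. Lcn2 passed in this comparison (1.19 ± 0.16, adjusted p = 0.0481). DESeq2 called 97 higher and 25 lower.

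Clustering gave 13 clusters. Clusters 1 and 2 were macrophage-like, led by Lpl, Pf4, Gpnmb and C1qc and by H2-Eb1, H2-Aa and Cd74; cluster 4 was monocyte-like, led by Vcan and Fpr2; and cluster 6 was patrolling monocyte-like, led by Ace, Adgre4 and Spn. Cluster 5, led by Arg1, Ccl24, Hilpda, Egln3, Thbs1 and Vegfa, stayed unnamed, as did clusters 3 (S100a8, Wfdc21, Lcn2), 7 (mitochondrial transcripts; median 1306 UMIs per cell), 8 (Serpinb1a, Prtn3, Ly6c2, Ifitm1), 9 (Ciita, H2-DMb1) and 13. T cell-like, B cell-like and neutrophil-like cells were few (10, 7 and 7 in the knockout library). The Ly6Chi sort gate sets what these shares can show.

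Cluster 5 held 5.88% of control 1 cells (exact 95% interval 5.18 to 6.64), 5.79% of control 3 cells (5.27 to 6.34) and 29.1% of knockout cells (27.8 to 30.5). Its leading genes include genes called between the groups, so this share restates the difference in their expression. When those genes were left out of the clustering, the best matching cluster (Jaccard index 0.482) held 24.2% (22.9 to 25.5), 12.6% (11.9 to 13.4) and 33.3% (31.9 to 34.7). That cluster was also the best match of macrophage-like cluster 1 (Jaccard index 0.319), so it merges cells of clusters 1 and 5 and does not give the share of cluster 5 alone. Low-UMI cluster 7 held 9.65%, 6.82% and 11.6% (10.7 to 12.6 in the knockout library), and cluster 8 held 7.29%, 6.18% and 3.63% (3.105 to 4.23), outside both controls also without the called genes (9.72%, 6.82% and 11.6%; 7.17%, 6.34% and 3.39%). Macrophage-like cluster 2 held 12.6%, 17.4% and 10.4%, below both controls, but without the called genes its match (Jaccard index 0.437) overlapped control 1 (4.86%, 10.1% and 3.99%). For clusters 1, 3, 4, 6 and 9 the controls differed from each other and the knockout interval overlapped a control or lay between them; the monocyte-like cluster 4, for example, held 5.49%, 20.8% and 7.65%. With 2 control libraries and 1 knockout library a permutation of library labels cannot give a p under 1 in 3, so none is given.

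**Figure D2:**
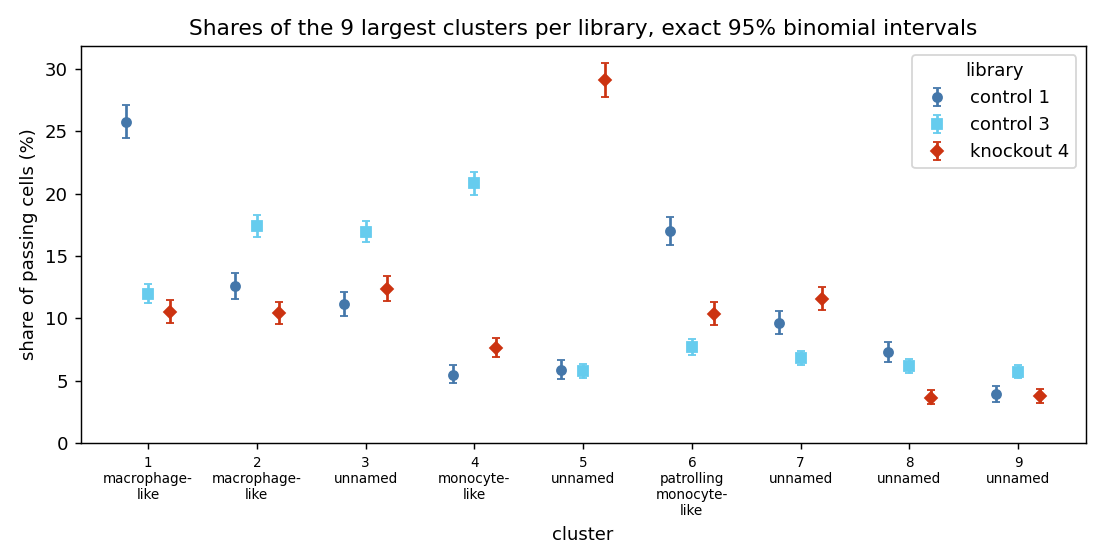
Share of passing cells (percent) in each of the 9 largest clusters for control 1, control 3 and knockout 4; bars are exact 95% binomial intervals and cover counting error only. Cluster 5 holds 29.1% of knockout cells against 5.88% and 5.79% of control cells, and shares of clusters 1 and 4 differ between the controls (25.8% and 12.0%; 5.49% and 20.8%).

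Within clusters, the glycolysis and hypoxia genes had medians above both controls throughout. The 27 genes that rose in the whole population were chosen from the sums of the same cells, so their values within clusters describe where the difference lay and are no repeat of it. Every tested member of the 27 lay above both controls in each of the 7 clusters tested (22 to 27 members per cluster), with median log2 fold changes from 0.97 in patrolling monocyte-like cluster 6 to 1.69 in low-UMI cluster 7. Hilpda, for example, stood at 60.8, 49.9 and 90.7 CPM in macrophage-like cluster 1, at 23.5, 17.1 and 54.2 CPM in monocyte-like cluster 4 and at 107, 100 and 320 CPM in cluster 5. Cxcl3 stood at 0.77 ± 0.18 in cluster 1, 3.14 ± 0.22 in cluster 2, 3.62 ± 0.24 in cluster 5 and 4.21 ± 0.38 in cluster 7. The difference between clusters was not tested. Glycolysis and hypoxia genes had medians between 0.56 and 0.78 in all 7 clusters. NRF2 and antioxidant genes had medians from 0.08 to 0.41 and ribosomal protein genes from -0.24 to -0.03. Cxcl9 fell in cluster 2 (42.1, 49.7 and 3.66 CPM; -3.65 ± 0.32) and in cluster 6 (47.5, 93.2 and 0.346 CPM).

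The number of genes that passed in a cluster, higher and lower, was 17 and 2 in cluster 2, 15 and 3 in cluster 5, 32 and 17 in cluster 6 and 50 and 3 in cluster 7. In clusters 1, 3 and 4 edgeR called 0 genes, with 903 of 11939, 623 of 10534 and 579 of 9529 tested at an unadjusted p under 0.05. DESeq2 called 15 higher and 7 lower, 3 and 1, and 9 and 3 there. In cluster 6 Lyz2 fell by 1.18 ± 0.17 (edgeR, adjusted p = 0.00239), and DESeq2 called only 1 higher and 2 lower genes there.

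**Figure D3:**
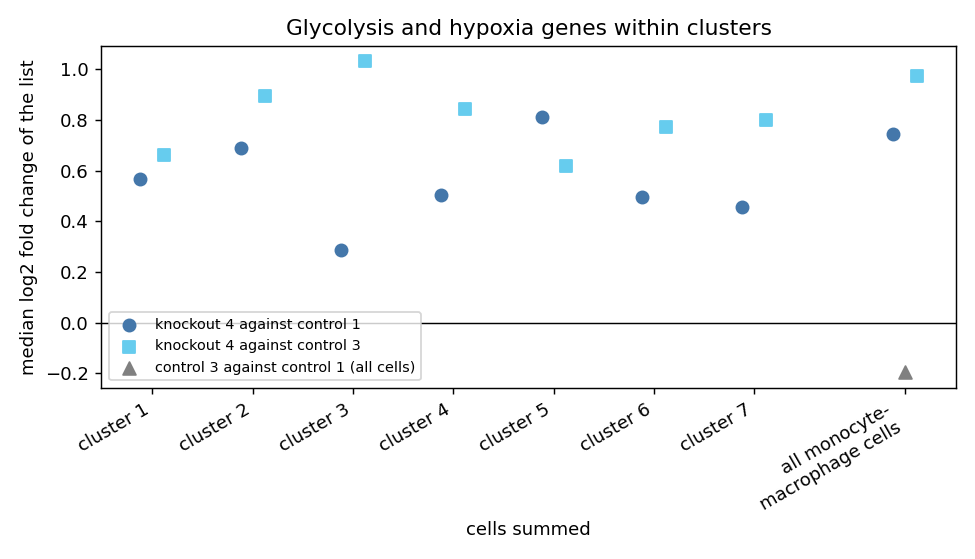
Median log2 fold change of the glycolysis and hypoxia genes (24 or 25 per cluster) of the knockout library against each control, within each cluster tested and over all monocyte-macrophage cells, with control 3 against control 1 shown for all cells. All knockout medians are positive, the lowest 0.29 in cluster 3 against control 1, and the controls differ by -0.20.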

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

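The median of the neutrophil-like monocyte list was positive in 4 of the 7 clusters tested and negative in the others. Clusters 3 and 2 had medians over 0.25 from 0 against each control, in opposite directions. In cluster 3, led by S100a8, Wfdc21 and Lcn2, the list median of the knockout library was 0.37 over 21 genes (0.37 against control 1, 0.47 against control 3). In macrophage-like cluster 2 it was -0.63 over 20 genes (-0.51 and -0.67). The medians of these clusters differed by 1.00, and every library comparison went one way in the first cluster and the other way in the second. In cluster 3 none of the genes passed the test, and in cluster 2 the 1 gene that passed, S100a9, was higher (2.57 ± 0.23), against the sign of the median. The highest median was that of low-UMI cluster 7, at 0.59 (1.05 against control 1, 0.20 against control 3), where 3 genes were called higher. The difference between the clusters was not tested. Genes of the list lead cluster 3, so its cells were grouped partly by the genes compared. Both clusters also depended on the clustering. Their best matches had Jaccard indices of 0.455 (cluster 3) and 0.437 (cluster 2) without the called genes. At resolution 0.4 these were 0.639 and 0.707, and at resolution 1.2 they were 0.806 and 0.405.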

How the results depend on the processing

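No paired analysis was possible with 1 knockout library. The library numbers (1 and 3 for control, 4 for knockout) do not say whether any libraries belong together. Sums without the low-UMI cluster, without cells of high UMI count and without cluster 5 were chosen after seeing the data, as was running the cell type lists through the settings; the other settings were fixed beforehand. Keeping doublets repeats the main values by construction, since 0 were removed, and is among the settings counted here. Where no reason is given, the cause was not tested. The 13 named genes that passed kept their direction in all 181 values under other settings and lost the call in 32. Their naming rule, like that of the next genes in order of p, required the same direction against each control. The 26 of the 181 values with a control left out therefore could not turn. Of 1321 values of the 95 genes named for the comparison and the functional lists 6 had the opposite sign, none of them with a control left out. Of the 48 genes named only as cell type markers 44 of 535 values had the opposite sign, and 16 of 96 with a control left out. Among the 82 of the 95 that did not pass, values over 1.5 times apart from those given numbered 30 without cluster 5, 38 of 76 in the monocyte-like cluster only, and 14 and 18 without control 1 and control 3. Among monocyte-macrophage cells DESeq2 called 98 genes higher and 21 lower (27 and 1 with edgeR), and edgeR without a low-count filter 289 and 161; the number lower was 2 with RLE factors, 4 with all barcodes, 2 with the stricter cell filter and 2 without the low-UMI cluster. Without cells of high UMI count edgeR called 9 higher and 0 lower, with 1207 of 14257 genes at an unadjusted p under 0.05 and 4.77 prior degrees of freedom. Without cluster 5 it called 0 and 0, with 629 of 14714 genes at that p and 5.34 prior degrees of freedom (6.41 in the comparison itself). In the monocyte-like cluster only it called 0 and 0, with 579 of 9529 genes at that p (DESeq2 9 and 3). Over all sorted cells DESeq2 called 97 and 25 and edgeR without the filter 288 and 164. Within clusters DESeq2 called, higher and lower, 15 and 7 in cluster 1, 22 and 4 in cluster 2, 3 and 1 in cluster 3, 9 and 3 in cluster 4, 12 and 1 in cluster 5, 1 and 2 in cluster 6 and 21 and 0 in cluster 7 (edgeR 50 and 3 in cluster 7, where 87 genes had an unadjusted p under 0.05 with DESeq2). Without the filter edgeR called 118 and 143 in cluster 1, 89 and 79 in cluster 2, 81 and 67 in cluster 3, 58 and 33 in cluster 4, 79 and 43 in cluster 5, 80 and 54 in cluster 6 and 76 and 8 in cluster 7. Lyz2 passed with DESeq2 (-1.004) and without the filter (-1.03), with adjusted p from 1.32e-07 to 0.776 over all settings. Leaving out a control gave values with no test, -1.005 to -0.26 for Commd10 and -1.19 to -0.81 for Lyz2. In the monocyte-like cluster alone Ccl24 stood at -0.42, Cxcl2 at -0.28 and Fn1 at -0.022, and list medians were 0.18 for inflammasome and IL-1, 0.047 for neutrophil-like monocyte and -0.069 for lipid-associated macrophage genes. Of the 8 list calls 3 were kept there, and those of neutrophil-like monocyte, lipid-associated macrophage, tissue repair, NF-kB and cell cycle genes were lost. Without cluster 5 Cxcl2 stood at -0.058, and medians were 0.034 for type I interferon response, 0.059 for lipid-associated macrophage (no longer called), 0.29 for MHC class II presentation, -0.019 for NF-kB targets (no longer called) and -0.072 for copper handling. With library totals the medians of NF-kB targets and lysosome genes were -0.036 and -0.046, and without the filter -0.015 and -0.022; the lysosome median was also -0.019 with the stricter cell filter and -0.019 without the low-UMI cluster. Commd5 stood at -0.017 in cells thinned to 3000 UMIs, and without cells of high UMI count Ube2c stood at -0.32 and the cell cycle median at -0.030. The cell cycle call was lost there and in thinned cells. Markers of the opposite sign were, with all barcodes, Cd79a 0.22, Fgb -0.18, Hba-a1 1.17, Hba-a2 1.14, Hbb-bs 1.16, Ly6d 0.92, Nkg7 -0.84 and Treml1 0.015; with the stricter cell filter Cd3d -0.012, Ebf1 -0.075, Fgb -0.041, Plac8 0.014 and Treml1 0.012; in thinned cells Ace 0.12, Cd5l 0.47, Fgb -0.083 and Treml4 0.057. Without the low-UMI cluster they were Cd3d -0.22, Ebf1 -0.084, Fgb -0.029, Plac8 0.0091 and Treml1 0.0041, and without cells of high UMI count Ace 0.019 and Treml1 0.051. Without cluster 5 they were Ace 0.25, Clec10a -0.068, Ebf1 -0.30, Plac8 0.20, Tnip3 -0.090, Treml1 0.018 and Treml4 0.24, and in the monocyte-like cluster only C1qb -0.65, Fgb -0.24, Il4i1 -0.090, Naaa -0.032, Plac8 0.20, Slc40a1 -0.041 and Tnip3 -0.025. Cox6a2 stood at -0.064 with DESeq2, -0.035 with library totals and -0.0073 without the filter, Cdh5 at -0.032 and -0.0099 in the last 2, and Ebf1 at -0.018 with library totals. Marker list medians of the opposite sign were B cell 0.16, NK cell -1.16, T cell 0.17 and erythroid 1.16 (called up) with all barcodes; Kupffer cell 0.46, T cell 1.36, endothelial 0.053, macrophage -0.16 and migratory DC 0.85 in thinned cells; T cell 1.03 and migratory DC 0.77 without cells of high UMI count; T cell 0.42, migratory DC 0.31 and patrolling monocyte 0.0045 without cluster 5; T cell 0.80, cDC2 0.24, macrophage -0.38 and plasma cell 0.36 in the monocyte-like cluster only; migratory DC 0.29 with the stricter filter; and NK cell -2.12, cDC1 0.0064 and migratory DC 0.062 without the low-count filter. Neutrophil markers were called up in 10 of 11 settings with a test, platelet markers in 9 of 9, and erythroid markers down in 8 of 10. Of the lists not called here, monocyte and T cell markers were called up and plasma cell markers down in 2 settings each, and cDC2 markers up and NK cell, stellate cell, macrophage and patrolling monocyte markers down in 1 each. The glycolysis and hypoxia median stayed between 0.56 and 0.97 and was called by preset camera in 11 of 11 other settings. With an estimated correlation 0 of 21 lists were called, with adjusted p of 0.557 for glycolysis and hypoxia, 0.557 for neutrophil-like monocyte and 0.811 for lipid-associated macrophage genes, and fry also called 0 (0.565, 0.615 and 0.916). The share of the cluster matching cluster 5, in control 1, control 3 and knockout 4, was 7.36%, 6.66% and 23.9% at resolution 1.2 and 12.0%, 7.43% and 42.4% with the stricter cell filter; at resolution 0.4 it was 3.17% in control 3 and 27.3% in knockout 4. Without the genes called between groups it was 24.2%, 12.6% and 33.3%, in a cluster that merges cells of clusters 1 and 5. Centring each library gave 24.2%, 22.1% and 25.1%, in a cluster that overlapped cluster 5 little (Jaccard index 0.240) and macrophage-like cluster 1 more (0.527). The knockout library had the fewest UMIs, and in simulated data of this depth 66.4% of genes changed by 1 log2 unit were called. Smaller changes can thus have been missed. Larger ones can have been missed too in genes that vary more than the simulated ones.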

Other observations

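Gbp2 and Serpina3g, which like Cxcl9 are known to be induced by interferon gamma, were each lower in 2 clusters of the knockout library. They were chosen after their values were seen, and no list of such genes was tested. Gbp2, a guanylate-binding GTPase, stood at 51.0, 32.0 and 7.32 CPM (in every such triplet control 1, control 3 and knockout 4) in macrophage-like cluster 2, a log2 fold change of -2.49 ± 0.37 (SE; 2 control and 1 knockout libraries; edgeR, adjusted p = 0.0356), and fell by 1.19 ± 0.23 in patrolling monocyte-like cluster 6 (adjusted p = 0.0254). Serpina3g, a serine protease inhibitor, fell by 3.30 ± 0.59 in cluster 5 and by 1.79 ± 0.38 in cluster 6. Over all monocyte-macrophage cells neither passed with edgeR (Gbp2 -1.04 ± 0.18, adjusted p = 0.0925, and Serpina3g -1.51 ± 0.34, adjusted p = 0.213). The related Cxcl10 (95.2, 106 and 88.8 CPM, -0.18 ± 0.16) and Irf1 (-0.36 ± 0.15) did not pass either. The calls within clusters depended on the tool. DESeq2 called 4 genes lower in cluster 2, 1 in cluster 5 and 2 in cluster 6, where edgeR called 2, 3 and 17. Whether Gbp2 and Serpina3g were among those of DESeq2 is not reported here.

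Of the tests that follow, the one on free RNA was written before its result was seen, and all others were chosen after. Glycolysis and hypoxia genes were higher in the knockout library, which also held more cells of cluster 5. A larger share of that cluster alone would leave the list median near 0 within clusters. Instead it lay above both controls within each of 7 clusters, the lowest being 0.29 (cluster 3 against control 1). Genes of the list lead cluster 5 and doublets were not removed, so an influence of its cells on the other clusters is not excluded. RNA freed from other cells and shared by all droplets was taken to add the same number of UMIs to each cell. It could then account for 9.98% of the excess over all clusters, or for 51.2% without the low-UMI cluster. An amount of free RNA that differs between droplets is not covered by this test, so free RNA stays open. A property of this library other than genotype, such as handling or the extent of injury, cannot be told apart from the genotype with 1 knockout library; the controls differed by -0.20. The real grouping gave 28 calls and the highest of the others 3, with 3 splits in all, too few for a share under 0.05. The other splits put the knockout library beside a control, where any difference of that library adds to the spread and lowers the calls. The comparison of these numbers therefore cannot decide whether the calls arose by chance.

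Lyz2 was lower in the knockout library. A different mix of clusters cannot account for it, since the value nearest to 0 in any cluster, against either control, was -0.61. A candidate explanation is that the Cre driver, inserted at Lyz2, takes 1 of 2 copies of the gene, which would give a log2 fold change near -1 in every cluster; the farthest from -1 was -0.68, in low-UMI cluster 7. The labels do not give the number of driver copies, so this remains a hypothesis.

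Lyz1, the neighbouring lysozyme gene (chromosome 10, 117287797 to 117292868), differed between the control libraries, at 6.59 CPM in control 1, 224 CPM in control 3 and 73.9 CPM in knockout 4; it was chosen after its values were seen. The mix of clusters cannot account for this, since control 3 exceeded control 1 by a log2 ratio of at least 4.12 in each of 7 clusters. Nor can a fixed share of Lyz2 counts assigned to this close copy, since Lyz1 counts as a percent of Lyz2 counts differed 43.9 times between libraries (0.0439%, 1.93% and 1.12%). A difference between the mice, such as a sequence variant at this locus, may remain; it was not tested.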
